A study of Homo sapiens with 36 samples.

How the data were processed

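Chromatin immunoprecipitation followed by sequencing was carried out on K562 cells for macroH2A1, macroH2A1.2 and γH2AX, per the labels. Crosslinked nuclei were digested with micrococcal nuclease and sonicated briefly before precipitation, per the labels' protocols. The authors deposited 1 list of enriched regions, called islands, for each of 22 libraries, and 14 input libraries listed in the series were not analysed here. Each island has its chromosome, start, end and the number of reads in it, so the deposited values are whole-number counts of reads per island, not scaled to library size. Bowtie2 2.1.0, SICER 1.1 and deepTools and the hg19 genome build are named in the submitters' processing notes, without a role or an order. A window of 200 bp, a gap of 600 bp and a false discovery rate of 0.01 are written in the names the authors gave the deposited lists. Islands were listed library by library. In the list of the control knockdown the name also carries the words merged and sorted, and what was merged is not given in the sources used here.

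Every island edge lay on a grid of 200 bp (0 islands off it). Islands on chromosomes Y and M were left out, which left chromosomes 1 to 22 and X, with a span of 3035 Mb up to the last island end. No filter for mappability or for regions of known artefact signal was applied here. The total number of reads sequenced per library is not in the lists and is unknown here. A list also holds no value outside its islands. Covered length, the sum of island lengths, was therefore the main measure. Reads in islands ranged from 2.02e6 to 75.2e6 per library and reads per kb of island from 33.4 to 180, and a library with more reads can pass the calling threshold at weaker places. No interval from read counts is given for a covered length, since calling error is not counting error. Replicate lists were compared before averaging, and the pair that shared most had 13 islands with equal edges and equal reads, 0.0366% of the shorter list, so all were kept as separate libraries.

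Groups came from the titles, which give the target, the treatment and a replicate number. The titles follow 4 naming styles, called title sets 1 to 4 here, which may be separate experiments. Set 1 holds macroH2A1 and γH2AX, set 2 macroH2A1.2 and γH2AX, set 3 γH2AX in K562 and in a line named 2A3, and set 4 macroH2A1.2 after 2 short hairpin RNAs. The aphidicolin titles of set 1 carry the number 0.5 without a unit. What 2A3 is was not taken from any source. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

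The comparisons, tests, alternatives and the rule for named regions were fixed before the data were examined. Covered lengths were compared as the log2 ratio of geometric means with an exact permutation test, two-sided, in which treatment labels were exchanged within title sets. With 2 libraries against 2 the smallest possible p is 0.333. Overlap of γH2AX with macroH2A was the percent of γH2AX island length inside macroH2A islands of the library with the same title stem. It was divided by its mean over 1000 circular shifts of the islands within each chromosome, with a fixed seed, and put on the log2 scale.

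Positions were compared in 30367 windows of 100 kb. The percent of each window inside islands was fitted with limma 3.58.1, with title set as a term for γH2AX, and p was adjusted by the Benjamini-Hochberg method at 0.05. Windows covered in fewer than 2 libraries of a fit were left out. Where all libraries of both groups were identical in a window, its standard error came only from the spread shared over all windows, so the SD and adjusted p are given. The named windows were the 10 with the largest mean difference in each direction among those past adjusted p 0.05 in which, within every title set, all aphidicolin libraries lay on 1 side of all untreated ones. Regions gained were covered in both aphidicolin libraries and neither untreated one for macroH2A, and in at least 4 of 5 against at most 1 of 5 for γH2AX, and regions lost the reverse. Where 1 library stood against 1, no test was made, except that the effect in set 3 was compared with sets 1 and 2 in a limma fit whose spread came from sets 1 and 2 alone.

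The only reference table given holds gene positions of another build (GRCh38.p14), and coordinates were not converted. Islands were therefore not placed on genes, and no exon or intron is stated. Tests of gene lists, such as common fragile site genes, and comparisons of long genes were not run for this reason. The table was used only for the number of protein-coding genes per chromosome.

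The alternatives were equal covered length (each library kept its islands in order of reads per kb up to the shortest covered length of the fit), longer islands, the upper 50% of islands by reads per kb, autosomes only, number of islands, reads in islands, an arcsine scale, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on island reads per window, no filter, limma with trend and robust, a replicate block, no title set, other overlap rules, and leaving out each library. Window fits of title sets 1 and 2 only and of 1 and 3 only, and leaving out chromosomes 9, 13 and 22, were chosen after seeing the data. Each window fit was tested on simulated data: 200 windows raised by 40 percentage points were recovered in 77.0% of cases for γH2AX, 51.5% for macroH2A1.2 and 58.5% for macroH2A1, and those raised by 10 points in 18.5%, 0% and 0%. Scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and under R 4.3.3.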

Results

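Genome occupancy was measured in K562, an established human chronic myeloid leukaemia line, for 3 chromatin targets. MacroH2A1 is a histone H2A variant with a large C-terminal macro domain, and macroH2A1.2 is one of its splice isoforms. γH2AX is the phosphorylated form of the variant H2AX that marks damaged DNA. Cells were untreated or received aphidicolin, an inhibitor of replicative DNA polymerases that slows replication forks and so causes replication stress. The series asks how macroH2A1.2 and γH2AX are placed before and after replication stress, and after loss of macroH2A1.2. There were 2 untreated and 2 aphidicolin libraries for macroH2A1 (title set 1) and for macroH2A1.2 (set 2). For γH2AX in K562 there were 5 and 5, with 2 of each in set 1, 2 of each in set 2 and 1 of each in set 3. Line 2A3 had 1 γH2AX library per treatment, and macroH2A1.2 was also profiled in 1 library with a control hairpin (sh-RFP) and 1 with a hairpin against macroH2A1.2 (sh-mH1.2). Each library is a list of islands, broad enriched stretches in hg19 coordinates, with 3212 to 45244 islands per list. Reads in islands, in units of 1e6, ranged from 2.41 to 26.5 for γH2AX in K562, 39.0 to 48.7 for macroH2A1 and 9.64 to 12.5 for macroH2A1.2.

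γH2AX islands covered 63.5 ± 17.2 Mb in untreated K562 (SD, n = 5) and 155 ± 81.0 Mb under aphidicolin (n = 5), a ratio of geometric means of 2.19 (log2 1.13). The mean number of islands was 10590 ± 3887 in untreated and 22191 ± 10598 in aphidicolin cells. The difference in covered length did not pass the test (exact permutation p = 0.0556, two-sided, 72 assignments, smallest possible 0.0278). Within title sets the log2 ratio was 1.67 in set 1, 0.78 in set 2 and 0.74 in set 3, which with 2 against 2 or 1 against 1 libraries cannot reach 0.05. Aphidicolin replicate 3 of set 2 covered 72.8 Mb, within the range of untreated libraries, while the other 3 aphidicolin libraries of sets 1 and 2 covered 180 to 235 Mb. Without that library the log2 ratio was 1.43 (exact permutation p = 0.0278).

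**Figure D1:**
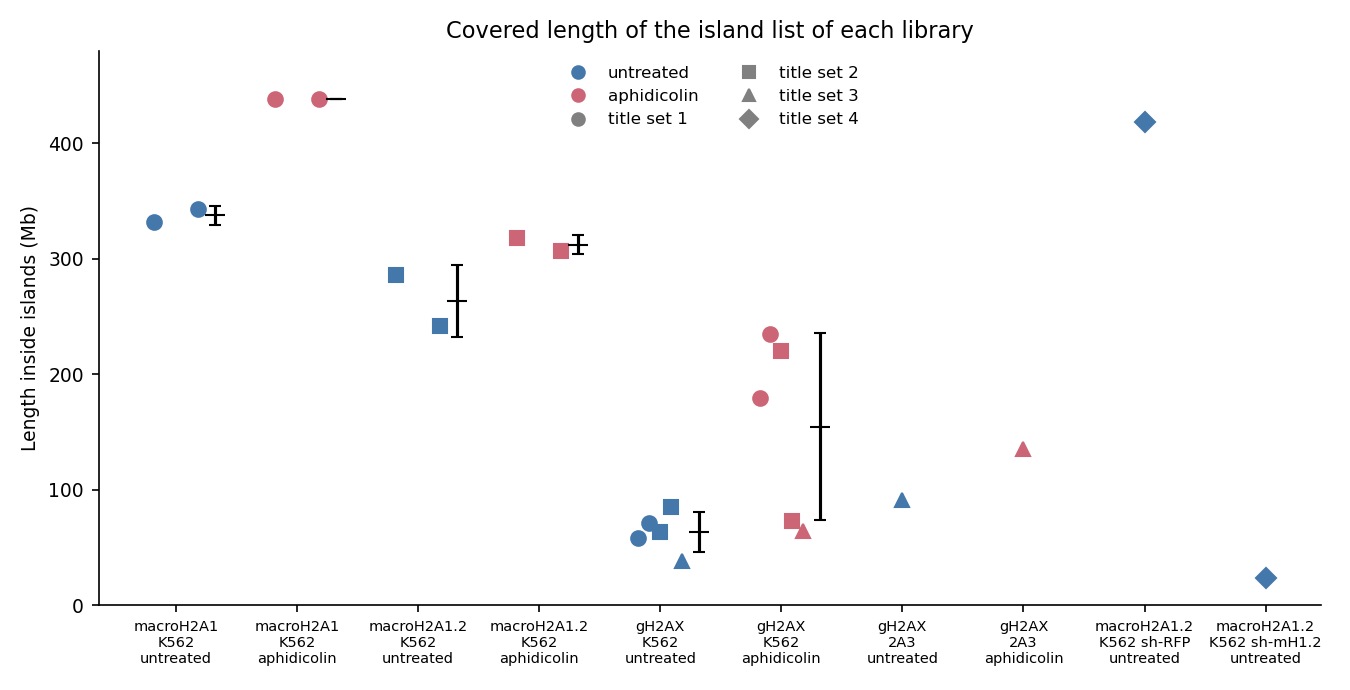
Length inside islands (Mb, vertical axis) for each of the 22 libraries, by target, line and treatment; each point is 1 library, its shape gives the title set, and the black bar with whiskers is the mean ± SD where a group has more than 1 library. γH2AX in K562 spreads from 64.6 to 235 Mb under aphidicolin and from 38.6 to 85.3 Mb without it, and macroH2A1.2 after sh-mH1.2 lies at 23.7 Mb.

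Under aphidicolin γH2AX rose in 511 of 13456 windows of 100 kb and fell in 180 (limma, adjusted p 0.05). In the windows that rose the median coverage was 0.76% in untreated and 45.3% in aphidicolin cells, and in those that fell 31.9% and 0.64%. Chromosome 22 stood apart, with 36 of its 105 tested windows higher (34.3%) and 0 lower, and it held 9 of the 10 named rises. The windows from 19500001 to 19700000 and from 22900001 to 23600000 on chromosome 22 were at 0% in all 5 untreated libraries. Under aphidicolin their mean coverage lay between 98.7 and 100% (adjusted p = 6.82e-09 for each, limma). The other named rise was chromosome 1, 228700001 to 228800000, from 2.92 ± 6.53% to 91.7 ± 3.13% (n = 5 each, adjusted p = 1.05e-05, limma). K562 carries extra copies of a fusion of chromosomes 9 and 22, and the segment from 22200001 to 23500000 was read-dense in each of the 8 macroH2A lists of untreated and aphidicolin K562, at 3.70 to 5.01 times the mean reads per kb of island. The same segment was 97.4% covered by γH2AX in untreated 2A3 and 31.0% in untreated K562 of set 3, and 0% in untreated K562 of sets 1 and 2.

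Of the 180 windows that fell, 46 also separated the treatments within every title set. The 10 largest falls of γH2AX among these lay on chromosomes 3, 6, 7 and 18. The window at chromosome 6, 57400001 to 57500000, went from 71.6 ± 27.8% to 2.20 ± 4.92% (n = 5 each, adjusted p = 0.0216, limma). Chromosome 7 held 6 of the 10, among them 3 adjoining windows from 145900001 to 146200000, whose means fell from between 46.1 and 50.2% to between 1.72 and 2.52%. On the same chromosome the window from 61700001 to 61800000 fell from 53.6 ± 28.5% to 0% (adjusted p = 0.0398, limma). The macroH2A1.2 list after sh-mH1.2 covered 39.0% of the 1-Mb bin around it, 61000001 to 62000000. It covered 1.62 to 6.76% of the 1-Mb bins that hold the other named falls of chromosome 7. Chromosome 13 had 8 of 80 tested windows lower and 0 higher. The counts moved by more than 1.5 times when any 1 of the 10 libraries was left out: 34 to 59 higher and at most 2 lower without an aphidicolin library of set 1 or any untreated library of sets 1 and 2, 206 and 4 without aphidicolin replicate 1 of set 2, 2215 and 298 without its replicate 3, and 2245 to 2268 and 1005 to 1021 without either library of set 3. With equal covered length limma called 49 higher and 8 lower, while at an unadjusted p under 0.05 the balance turned (686 higher and 985 lower), and on island reads edgeR called 3780 and 1695 and DESeq2 5997 and 2867.

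Untreated and aphidicolin γH2AX islands occupied different places in sets 1 and 2. Shared bases made up 1.53% of the bases in either list between treatments in set 1 and 3.53% in set 2. Between replicates they made up 24.8% (untreated) and 46.5% (aphidicolin) in set 1 and 27.8% and 21.7% in set 2. In set 3 the 2 treatments shared 26.3%. Part of the untreated islands of sets 1 and 2 lay in segments many Mb long, described here after their values were seen. Of 1529 bins of 2 Mb, 99 had at least 10% untreated coverage and 1012 under 1%. Chromosome 7 had the highest untreated coverage in these sets, 8.21%. The 2 longest runs of 2-Mb bins on chromosome 7 with a mean of at least 10% are given here. From 76000001 to 90000000 untreated coverage in sets 1 and 2 was 27.4 ± 11.1% against 3.44 ± 1.48% under aphidicolin (n = 4 each). From 108000001 to 128000000 it was 24.5 ± 9.61% against 4.21 ± 0.779%. MacroH2A1 covered 2.70 ± 0.0879% of the first and 5.21 ± 0.213% of the second segment in untreated cells (n = 2), against 13.1% of the chromosome. For macroH2A1.2 the values were 4.21 ± 0.804% and 8.40 ± 2.26% (n = 2), against 11.1% of the chromosome. The densest untreated γH2AX bin of 2 Mb was chromosome 13, 90000001 to 92000000, with a mean of 77.9% in untreated libraries of sets 1 and 2 and 0% in untreated set 3. Of the aphidicolin libraries of sets 1 and 2, 3 had 0% of chromosome 13, 90400001 to 92500000, and replicate 3 of set 2 had 60.0%.

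**Figure D2:**
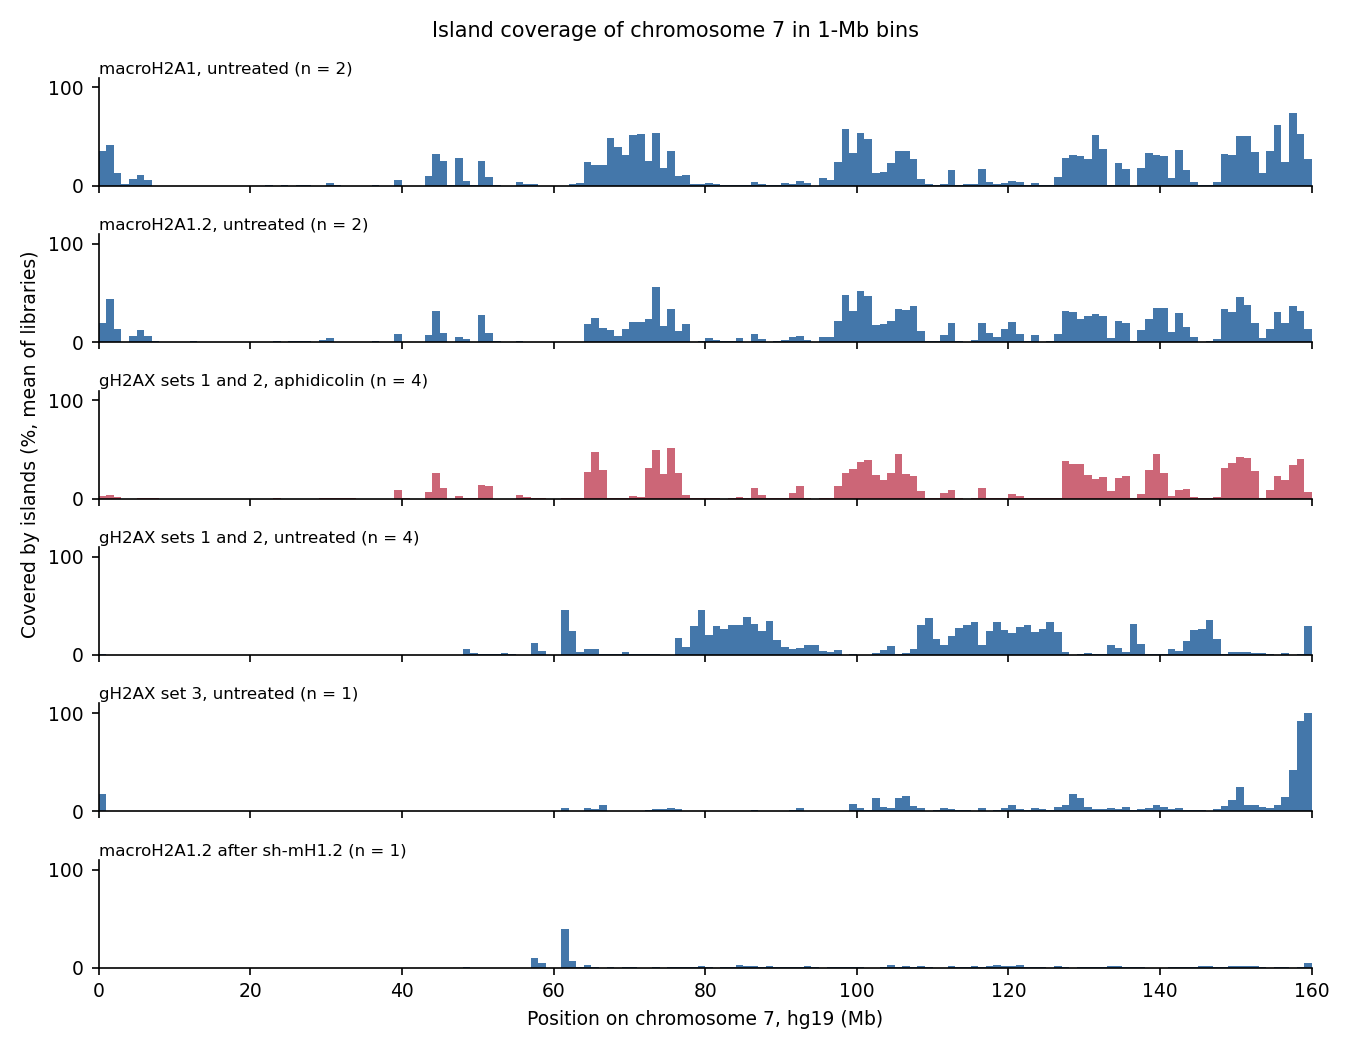
Percent of each 1-Mb bin of chromosome 7 inside islands (vertical axis, mean over the libraries of a group) against position in Mb (hg19), for 6 groups, blue without and red with aphidicolin. Aphidicolin γH2AX of sets 1 and 2 peaks at many places where macroH2A peaks, but not all. From 67000001 to 72000000 macroH2A1 covers 30.8 to 52.3% of the bins and aphidicolin γH2AX 0.345 to 2.71%. Untreated γH2AX of sets 1 and 2 is spread over the segments from 76 to 90 Mb and from 108 to 128 Mb. It is also high elsewhere, with 45.5% from 61000001 to 62000000. The untreated set 3 library peaks at the end of the long arm.

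**Figure D3:**
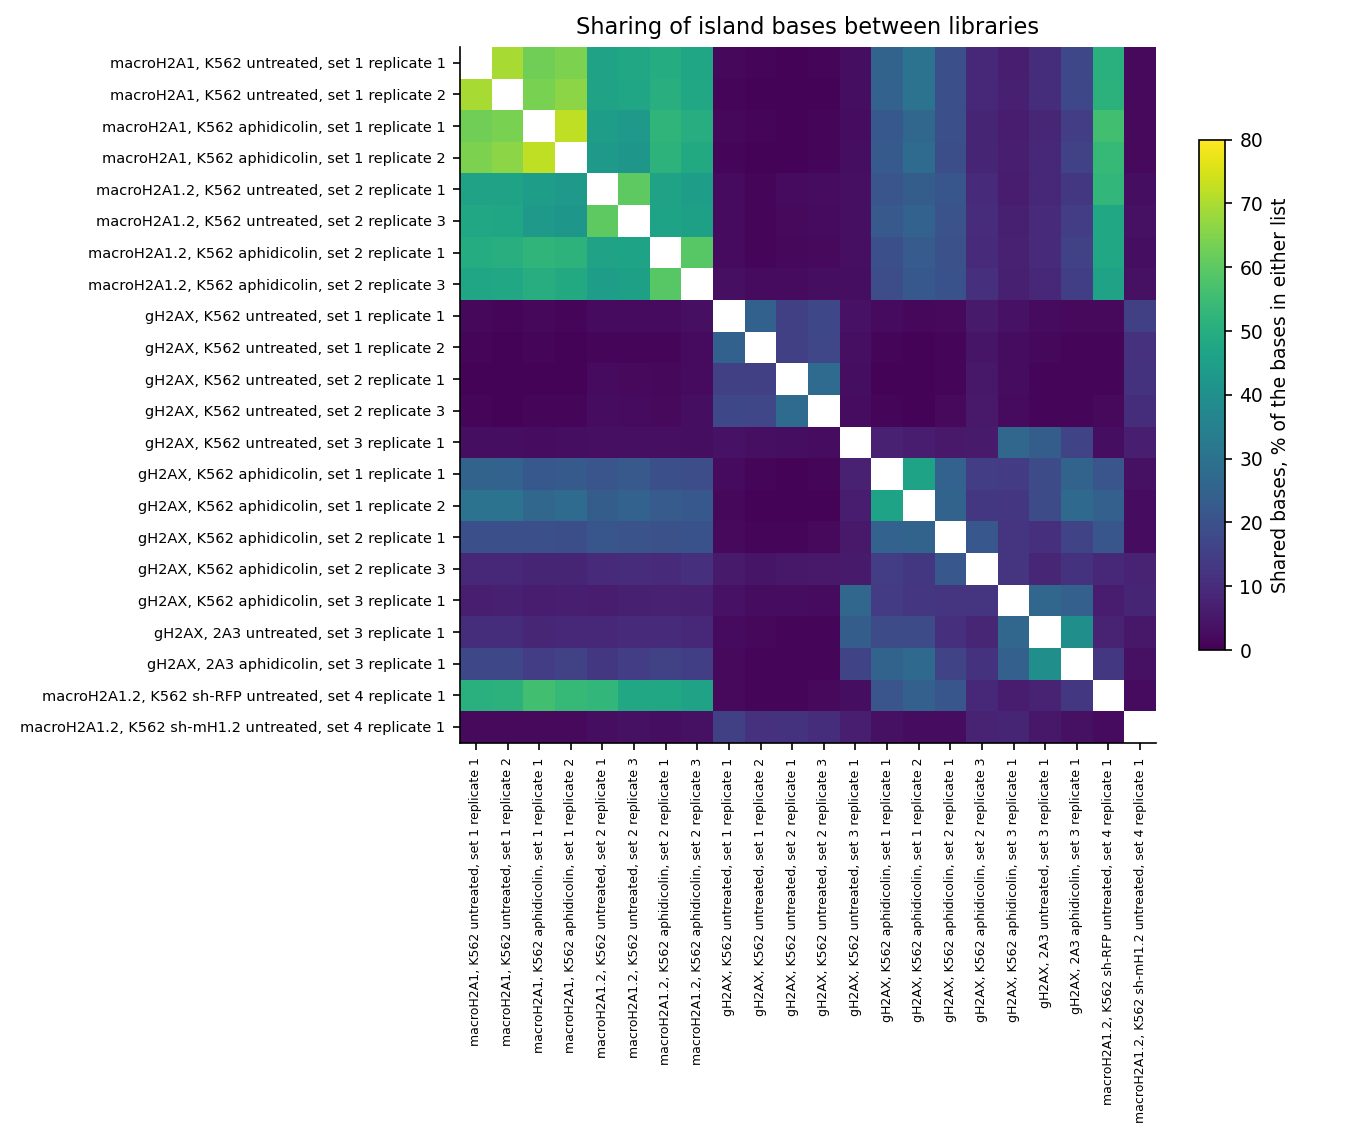
Bases shared by each pair of the 22 libraries as a percent of the bases in either list (colour; the diagonal is left white). Replicates of macroH2A1 share 69.5% untreated and 72.5% under aphidicolin, and untreated and aphidicolin γH2AX share a mean of 1.53% in set 1 and 3.53% in set 2.

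Much of the γH2AX length lay inside macroH2A islands in aphidicolin libraries, and in untreated libraries of sets 1 and 2 about as much as or less than after shifting. Of the γH2AX length in set 1 aphidicolin libraries, 62.4% (replicate 1) and 62.4% (replicate 2) fell inside macroH2A1 islands, against 18.6% and 18.8% after shifting. In set 2 aphidicolin libraries 40.4% (replicate 1) and 50.2% (replicate 3) fell inside macroH2A1.2 islands, against 13.6% and 12.9%. Untreated libraries had 11.1% and 5.36% inside macroH2A1 islands, against 11.6% and 11.9% after shifting, and 12.1% and 8.70% inside macroH2A1.2 islands, against 10.5% and 8.56%. On the log2 scale the ratio to shifted islands was 1.75 ± 0.16 under aphidicolin (n = 4) and -0.25 ± 0.61 without it (n = 4), a difference of 2.00. The exact permutation p was 0.0556, the smallest possible with 36 assignments, so the test could not pass 0.05. The difference was 2.35 for macroH2A1 in set 1 and 1.65 for macroH2A1.2 in set 2 (exact permutation p = 0.333 each, the smallest possible). Set 3 had no macroH2A library of its own. Against regions common to both untreated macroH2A1.2 libraries, its untreated K562 library stood at 1.36 (20.1% inside, 7.83% after shifting) and its aphidicolin library at 1.67, and 2A3 at 1.73 untreated (28.2%, 8.49% after shifting) and 1.78 under aphidicolin, while the 4 untreated libraries of sets 1 and 2 stood between -0.46 and 0.35 and the 4 aphidicolin ones between 1.81 and 2.1.

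**Figure D4:**
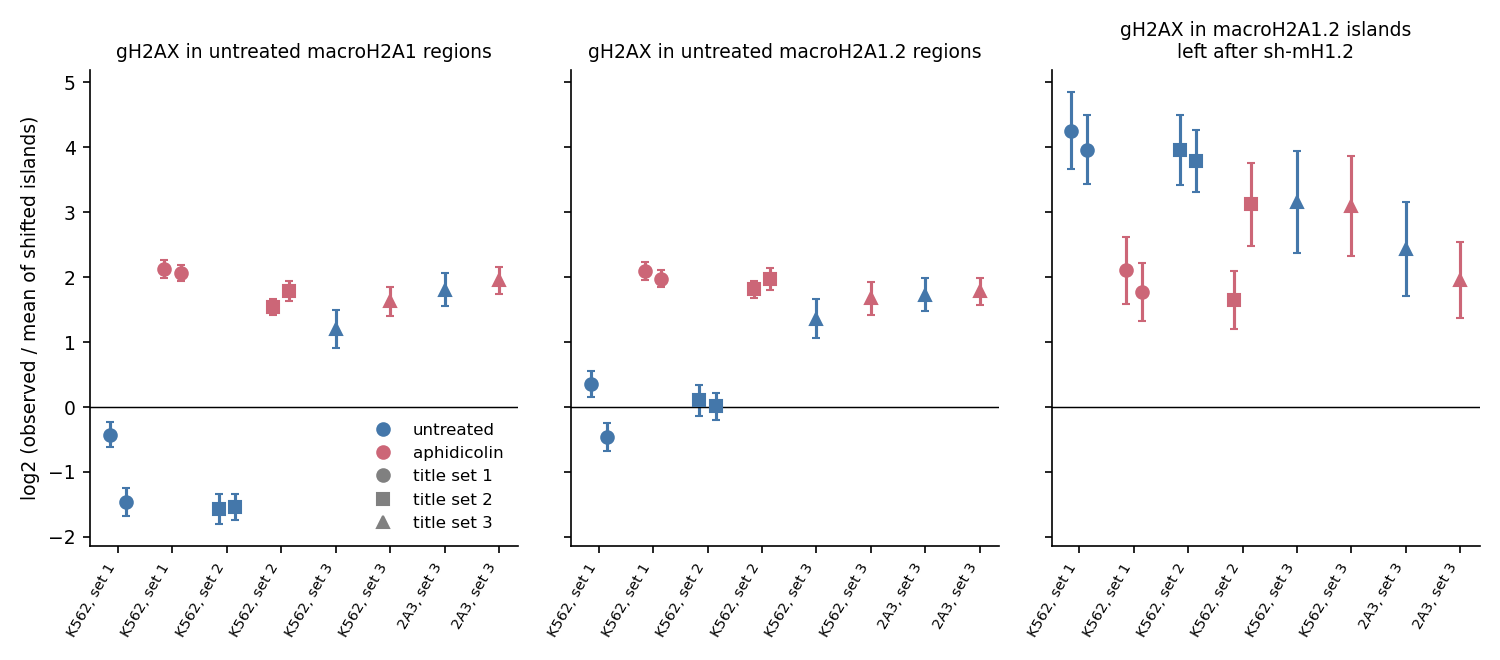
Log2 ratio of γH2AX length inside a set of regions to the mean of shifted γH2AX islands (vertical axis; 0 is the level of shifted islands) for each library; whiskers are the SD of the log2 ratio over 1000 shifts, not an error between replicates. In untreated macroH2A1.2 regions the aphidicolin libraries of sets 1 and 2 lie between 1.81 and 2.1 and the untreated ones between -0.46 and 0.35; in the islands left after sh-mH1.2 the untreated ones lie highest, between 3.79 and 4.26.

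MacroH2A1.2 changed place under aphidicolin in both directions. Its islands covered 264 ± 31.2 Mb in untreated and 312 ± 7.89 Mb in aphidicolin cells (n = 2 each, ratio 1.19, exact permutation p = 0.333, the smallest possible). Coverage rose in 1879 of 12335 windows and fell in 830 (limma, adjusted p 0.05). The largest rise, chromosome 10, 79900001 to 80000000, went from 5.60 ± 1.41% to 86.4 ± 3.68% (n = 2 each, adjusted p = 0.0116, limma), and the adjoining window to 80100000 went from 6.20 ± 2.55% to 76.8 ± 3.96%. Chromosome 7, 131400001 to 131500000, rose from 16.8 ± 1.41% to 92.8 ± 0.283%, and chromosome 3, 194500001 to 194600000, from 16.5 ± 2.97% to 89.6 ± 0.849%. The other named rises, from 68.1 to 74.3 points, lay on chromosomes 1, 6, 16 and 18. The largest fall, chromosome 1, 145000001 to 145100000, went from 96.5 ± 0.424% to 0% (adjusted p = 0.0116, limma). Of the 10 largest falls, 6 lay on chromosome 6, including 139900001 to 140000000 (94.3 ± 3.54% to 2.1 ± 2.97%) and 15100001 to 15200000 (86.6 ± 1.13% to 3.40 ± 1.13%). Chromosome 9, 133600001 to 133700000, within a segment that was read-dense in all macroH2A lists of K562 given aphidicolin or left untreated, fell from 83.3 ± 13.4% to 0%. Chromosome 19 had more falls (84 of 377 windows) than rises (30), and chromosomes 21 and 16 had the highest shares of rises, 24.4% and 23.8%.

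At the level of bases, 52.4 Mb were gained by macroH2A1.2 under aphidicolin and 32.3 Mb lost, 84.7 Mb together. The other 2 splits of the 4 libraries gave 15.7 and 15.6 Mb. With equal covered length the balance turned, with 31.8 Mb gained and 37.1 Mb lost, and limma called 854 windows higher and 1176 lower; edgeR on island reads called 1985 and 1681, and DESeq2 3086 and 3040. Limma called 770 windows higher and 482 lower without untreated replicate 3 and 0 when untreated replicate 1, aphidicolin replicate 1 or aphidicolin replicate 3 was left out (2609, 2224 and 2254 higher and 983, 1107 and 885 lower at an unadjusted p under 0.05).

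MacroH2A1 mostly gained coverage. Its islands covered 338 ± 8.05 Mb in untreated and 439 ± 0.0286 Mb in aphidicolin cells (n = 2 each, ratio 1.30, exact permutation p = 0.333, the smallest possible). Coverage rose in 852 of 12732 windows and fell in 14 (limma, adjusted p 0.05). Chromosome 22, 22700001 to 22900000, just before the windows named for γH2AX, held the largest rises, from 0% to 100% and to 97.1 ± 4.10% (n = 2 each, adjusted p = 0.0187 and 0.0379, limma). Chromosome 1, 245700001 to 245800000, rose from 9.10 ± 12.9% to 91.8 ± 8.20%, chromosome 16, 79000001 to 79100000, from 0% to 74.9 ± 13.2%, and chromosome 8, 86700001 to 86800000, from 0% to 73.6%. The window at chromosome 16, 46400001 to 46500000, was among the named rises of both antibodies, from 0% to 62.9 ± 1.27% for macroH2A1 and from 2.70 ± 3.82% to 75.9 ± 7.21% for macroH2A1.2. As no mappability filter was applied, a mapping artefact was not excluded at this or other named windows of any target. Falls were smaller: the largest, chromosome 16, 85300001 to 85400000, went from 73.1 ± 2.40% to 26.7 ± 7.78% (adjusted p = 0.0413, limma), and 3 of the 10 named falls lay on chromosome 19.

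MacroH2A1 gained 49.7 Mb and lost 5.09 Mb, 54.8 Mb together, against 17.0 and 16.1 Mb in the other 2 splits of its 4 libraries. MacroH2A1.2 and macroH2A1 gains shared 5.25 Mb and losses 0.690 Mb, against 0.857 and 0.0542 Mb for regions placed independently over the span. Opposite changes also shared more than that: 1.31 against 0.529 Mb (macroH2A1.2 lost, macroH2A1 gained) and 0.127 against 0.0879 Mb (the reverse). With equal covered length macroH2A1 gained 16.4 Mb and lost 15.2 Mb, and limma called 4 windows higher and 0 lower (800 and 891 at an unadjusted p under 0.05), edgeR 14 and 0, and DESeq2 2436 and 2715. Leaving out any 1 of the 4 libraries (untreated replicate 1 or 2, aphidicolin replicate 1 or 2) left 0 windows by limma in either direction, with 2444, 2758, 2817 and 2977 higher and 77, 65, 84 and 235 lower at an unadjusted p under 0.05.

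Few macroH2A1.2 islands were listed after the hairpin against it. The list after sh-mH1.2 held 3212 islands over 23.7 Mb and the list after sh-RFP 39096 islands over 418 Mb, so covered length was 5.67% and island number 8.22% of the control (1 library each, no test). Reads in islands were 2.02e6 against 75.2e6, and reads per kb of island 85.3 against 180. The sh-RFP list shared 50.4% of bases with untreated K562 macroH2A1.2 lists and the sh-mH1.2 list 3.34%, as means over 2 libraries. The 3 longest runs of 100-kb windows at least 50% covered after sh-mH1.2, a rule made after the values were seen, were chromosome 13, 90400001 to 92500000 (96.8% covered), chromosome 22, 22200001 to 23500000 (94.5%), and chromosome 9, 133600001 to 134200000 (91.0%). After sh-RFP they were covered 0%, 98.1% and 98.5%. As total reads per library are unknown, a lower depth after sh-mH1.2 was not excluded.

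Line 2A3 had more γH2AX coverage than K562 in set 3 at both treatments. Untreated 2A3 had 91.0 Mb in islands against 38.6 Mb in K562, 2.36 times as much, and under aphidicolin 135 against 64.6 Mb, 2.09 times as much (1 library each, no test). Aphidicolin over untreated was 1.48 in 2A3 and 1.67 in K562, and whether the 2 ratios differ was not tested. In both lines the set 3 islands covered a higher percent of the ends of long arms than of the rest. This was a relative excess, and most of the island length lay outside the ends. In 2A3 the ends were covered 37.2% untreated and 33.9% under aphidicolin, and the rest 2.47% and 3.99%. The last 2 Mb of the long arms were covered 19.4 times as much as the rest in untreated K562 and 15.1 times in untreated 2A3. Under aphidicolin the ratios were 9.46 and 8.50. In K562 the ends were covered 19.3% untreated and 17.8% under aphidicolin, and the rest 0.994% and 1.89%. In sets 1 and 2 this ratio was 0.771 to 1.12 in untreated and 1.95 to 3.37 in aphidicolin libraries.

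**Figure D5:**
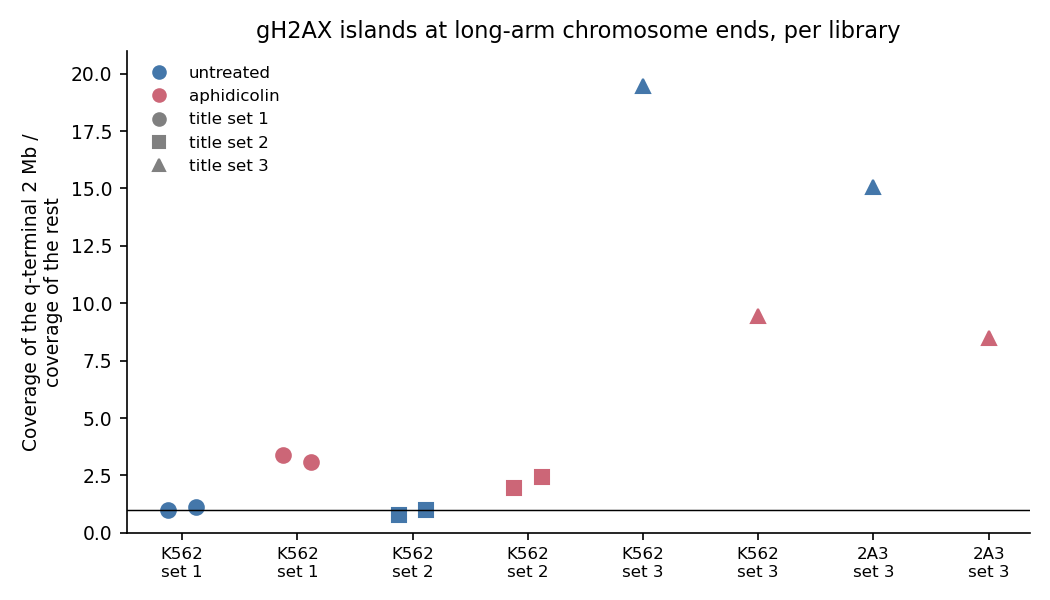
Coverage of the last 2 Mb of long arms by γH2AX islands divided by coverage of the rest of the chromosomes (vertical axis, line at 1) for each of the 12 γH2AX libraries, by line, title set and treatment. The 4 libraries of set 3 lie between 8.50 and 19.4, above the 8 of sets 1 and 2, which reach 3.37.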

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

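In this part the tests of the chromosome ends, of the knockdown list and of the untreated set 3 library were chosen after the result was seen, and the copy number test before. The ratio of γH2AX coverage at the ends of long arms to the rest lay, in set 3, far from the other libraries of its group. In the aphidicolin K562 library of set 3 the ends themselves did not stand out, at 17.8% against 5.75 to 25.2% in sets 1 and 2. Its coverage elsewhere was low, at 1.89% against 2.35 to 7.48%. The untreated one had 19.3% at the ends, against 1.93 to 2.63%, and 0.994% elsewhere, against 1.93 to 2.82%. The ratio of the last 2 Mb to the rest was 19.4 in the untreated K562 library of set 3, while the other 4 untreated libraries lay between 0.771 and 1.12, and 9.46 in its aphidicolin library, while the other 4 lay between 1.95 and 3.37. Of 16 groups and measures searched for such a library, 2 were past the critical value, and chance alone gives about 1 in 20. An excess carried by line 2A3 alone is argued against, since the lower of the 2 K562 libraries of set 3 already stood at 2.81 times the highest ratio of sets 1 and 2. All 4 libraries of set 3 shared it, the lowest at 2.52 times that highest ratio, which is consistent with something common to this title set. What that is stays open, no biological explanation was tested, and input libraries were not used here.

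The effect of aphidicolin on γH2AX in set 2 differed from that in set 1 in 1318 of 13100 windows (160 higher in set 2 and 1158 lower; limma interaction, adjusted p 0.05), and the effect in set 3 differed from the mean of sets 1 and 2 in 428 of 13456 windows (186 higher and 242 lower). Set 3 has 1 library per treatment in K562, so that second comparison assumes that they vary like those of sets 1 and 2, from which set 3 stood apart at chromosome ends, and its count alone does not show that the effects differ. The effect on macroH2A1.2 differed from that on macroH2A1 in 1458 of 14320 windows (449 higher and 1009 lower for macroH2A1.2), where the antibody and the title set change together.

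Untreated γH2AX islands of sets 1 and 2 lay below the level of shifted islands in untreated macroH2A1 regions (log2 ratio -1.57 to -0.42) and scattered around it in macroH2A1.2 regions (-0.46 to 0.35). A candidate explanation for part of them is background listed when an antibody finds little: in the islands left by macroH2A1.2 knockdown the untreated libraries stood at a mean log2 ratio of 3.99 (3.79 to 4.26) and the aphidicolin ones at 2.16 (1.65 to 3.12), a difference of 1.83, or 2.13 without chromosomes 9, 13 and 22. Those islands held 12.0 to 18.6% of the untreated γH2AX length (7.91 to 12.8% without these chromosomes) and covered 1.28% and 1.22% of the chromosome 7 segments, so for most of the length it stays open. The log2 ratio uses the share of each list's own length, so a longer list can lower it. Part of the 1.83 may come from length, and no equal-length version was run. Among aphidicolin lists of sets 1 and 2, the shortest (72.8 Mb) stood at 3.12 and the longest (235 Mb) at 1.77. Of the 3 longest runs left after sh-mH1.2, these untreated γH2AX libraries covered 96.7 to 96.8% on chromosome 13 and 0% on chromosomes 22 and 9. Background thus does not account for the runs on chromosomes 22 and 9. Copy number cannot be told apart from background elsewhere. The 10% quantile of reads per kb among short macroH2A islands was about equal in bins rich and poor in untreated γH2AX (ratios 0.986 to 1.00 in 4 libraries, interval of the highest 0.980 to 1.02). However, the calling threshold may fix that value. Whether the untreated state itself keeps γH2AX out of macroH2A regions cannot be told. It was not seen in the untreated libraries of set 3, which stood at 1.36 in K562 and 1.73 in 2A3 in macroH2A1.2 regions (SD of shifts 0.304 and 0.252). There is 1 such library per line, and the spread between replicates of set 3 is unknown. The macroH2A1.2 regions were those of K562 for both lines.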

How the results depend on the processing

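The window fits of title sets 1 and 2 only and of 1 and 3 only, and the setting without chromosomes 9, 13 and 22, were chosen after seeing the data, all other settings before. Covered length kept its direction under all alternatives run for the 3 targets. Its log2 ratio lay between 0.74 and 1.67 for γH2AX, 0.09 and 0.25 for macroH2A1.2 and 0.22 and 0.39 for macroH2A1. It ranged over the left-out libraries from 0.94 (without aphidicolin replicate 1 of set 2) to 1.43 (without aphidicolin replicate 3 of set 2, exact permutation p = 0.0278, the only γH2AX setting past 0.05) for γH2AX, 0.13 to 0.37 for macroH2A1.2 and 0.35 to 0.40 for macroH2A1. The overlap difference lay between 1.90 and 2.44 under the other settings and from 1.71 to 2.15 with 1 library left out, in a design that cannot pass 0.05. Deviations of libraries with the same replicate number were hardly correlated over windows (-0.06, 0.13, -0.09 and 0.01). With 2 libraries per treatment this cannot show whether the numbers mark pairs. With the replicate number as a block, covered length had exact permutation p = 0.125 for γH2AX and 0.5 for each macroH2A target and overlap 0.125; limma called 18 γH2AX windows higher and 0 lower (3119 and 1122 at unadjusted p under 0.05), 451 and 139 for macroH2A1.2, and 0 and 0 for macroH2A1 (3588 and 118 unadjusted). Of 868 values for named windows under alternatives, 495 stayed past the threshold, 372 did not and 1 reversed: macroH2A1 window on chromosome 12 starting at 94900001, at -5.5 points with equal covered length (adjusted p = 0.261, limma) against 59.2. The causes were not tested, except that by construction equal covered length keeps fewer islands, no filter tests more windows and leaving out a library leaves fewer samples. Gene-based alternatives, gene lists and long genes were not run, for want of an hg19 annotation. Unknown depth limits all comparisons of length, and the simulated data show that changes of 10 points are mostly missed. Simulated changes of 20 points were recovered in 43.5% of cases for γH2AX, 0% for macroH2A1.2 and 23.5% for macroH2A1.

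Counts of windows higher and lower by limma moved as follows. For γH2AX (511 and 180) they were 49 and 8 with equal covered length (686 and 985 unadjusted, where the balance turned), 4087 and 1417 on the arcsine scale, 26 and 1 with no filter, 2007 and 532 with trend and robust, 378 and 18 with no title set, 2306 and 1028 in title sets 1 and 2, 41 and 0 in sets 1 and 3 (2556 and 339 unadjusted) and 376 and 99 without chromosomes 9, 13 and 22; edgeR called 3780 and 1695 and DESeq2 5997 and 2867 on island reads. For macroH2A1.2 (1879 and 830) they were 854 and 1176 with equal covered length and 152 and 93 with no filter; edgeR called 1985 and 1681 and DESeq2 3086 and 3040. For macroH2A1 (852 and 14) they were 4 and 0 with equal covered length (800 and 891 unadjusted), 1206 and 53 on the arcsine scale, 76 and 16 with no filter and 0 and 0 with trend and robust (4259 and 169 unadjusted); edgeR called 14 and 0 (2085 and 1881 unadjusted) and DESeq2 2436 and 2715. Both antibodies in 1 fit gave 2498 and 174, and 64 and 115 with equal covered length, where the balance turned. The island read fits leave out reads outside islands, so their counts rest on the same calls.

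Leaving out 1 library (limma; edgeR and DESeq2 were not run this way), where a lone library in an arm was assumed to vary like the others, gave 34 to 2268 higher and 0 to 1021 lower for γH2AX. The values were 34 and 2 without untreated replicate 1 and 34 and 1 without untreated replicate 2 of set 1, 49 and 1 without aphidicolin replicate 1 and 59 and 1 without aphidicolin replicate 2 of set 1, 36 and 1 without untreated replicate 1 and 36 and 0 without untreated replicate 3 of set 2 (3049 and 1022 unadjusted), 206 and 4 without aphidicolin replicate 1 and 2215 and 298 without aphidicolin replicate 3 of set 2, and 2245 and 1005 without the untreated and 2268 and 1021 without the aphidicolin library of set 3. For macroH2A1.2 limma called 0 to 770 higher and 0 to 482 lower, with 770 and 482 without untreated replicate 3 and 0 without any of the other 3 (2224 to 2609 and 885 to 1107 unadjusted). For macroH2A1 it called 0 without any 1 of the 4 libraries (2444 to 2977 and 65 to 235 unadjusted).

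Gained and lost lengths moved too. For γH2AX (33.7 and 8.82 Mb) 10.3 Mb were gained and 17.5 Mb changed with equal covered length, and 53.3 and 65.9 Mb with whole islands shared at 1 bp. For macroH2A1.2 (52.4 and 32.3 Mb) 31.8 Mb were gained with equal covered length and 19.7 Mb lost at 1 bp, and the other splits changed 15.7 and 15.6 Mb. For macroH2A1 (49.7 and 5.09 Mb) 16.4 Mb were gained, 15.2 Mb lost and 31.6 Mb changed with equal covered length, 28.2, 1.86 and 30.1 Mb at 1 bp and 2.61 Mb were lost at 50%, and the other splits changed 17.0 and 16.1 Mb. The log2 ratio after sh-mH1.2 was -4.14 for covered length, -3.61 for islands and -5.22 for reads. For the 4 ratios of set 3 (2A3 over K562, and aphidicolin over untreated) each alternative moved the log2 value by less than 0.86. That is the SD of a log2 ratio of 2 γH2AX replicate libraries. The log2 ratios of aphidicolin over untreated, 0.74 in K562 and 0.57 in 2A3, lie under this SD themselves. Those of 2A3 over K562, 1.24 untreated and 1.06 under aphidicolin, lie not far above it.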

Other observations

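In this part the comparisons of the first 2 paragraphs and the splits within title sets were chosen after seeing the data, and the other tests before. γH2AX covered stable macroH2A1.2 regions more than moving ones, but without aphidicolin in sets 1 and 2 only at about the level of the whole span. Regions inside macroH2A1.2 islands in all 4 libraries (135 Mb) were covered 45.8% and 36.9% by aphidicolin γH2AX replicates 2 and 1 of set 1 and 39.2% and 14.9% by replicates 1 and 3 of set 2. Regions gained by macroH2A1.2 were covered 21.5%, 15.3%, 18.2% and 8.11% by the same libraries, and regions lost 32.2%, 26.7%, 22.5% and 5.61%, against 7.75%, 5.92%, 7.27% and 2.40% of the whole span. The aphidicolin libraries of set 3 covered 10.2% of kept, 7.31% of gained and 4.24% of lost regions in K562, and 24.5%, 17.6% and 9.80% in 2A3. Untreated libraries of sets 1 and 2 covered 1.99 to 3.08% of kept, 1.16 to 2.78% of gained and 0.462 to 2.05% of lost regions. Their share of the whole span was 1.93 to 2.81%. Kept and gained regions were close in replicate 1 of set 1 (2.84 and 2.78%). In replicate 2 of set 1 kept regions lay under the span (1.99 against 2.35%). In untreated set 3 the values were 4.27%, 2.72% and 2.75% in K562 and 15.3%, 8.70% and 7.11% in 2A3. Kept macroH2A1.2 regions were covered most in each of the 12 γH2AX libraries, and lost against gained regions had no common order. The list after sh-mH1.2 also covered kept regions most (5.19%, against 1.47% of gained and 1.53% of lost). The sh-RFP list covered 95.8% of kept, 81.3% of lost and 51.2% of gained macroH2A1.2 regions. For macroH2A1, kept regions were covered least in each untreated library of sets 1 and 2. The values were 0.729 to 1.47% of kept, 1.36 to 2.28% of gained and 1.06 to 2.72% of lost regions. Untreated 2A3 covered 13.6% of kept, 4.32% of gained and 15.4% of lost macroH2A1 regions. In untreated K562 of set 3 and all aphidicolin libraries, kept macroH2A1 regions were covered most.

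Across 23 chromosomes, macroH2A coverage went with the number of protein-coding genes per Mb (gene numbers from GRCh38.p14, span from the islands; 12 relations computed, and chromosomes are not independent replicates). For untreated macroH2A1.2 Pearson's r was 0.86 and Spearman's rho 0.83 (permutation p = 1e-05 each, the smallest that 100000 resamples give, adjusted 2.4e-05 and 6e-05), and r was 0.84 without chromosomes 17 and 19. Aphidicolin γH2AX of sets 1 and 2 had r = 0.65 (permutation p = 2e-05, adjusted 4e-05) and rho = 0.76 (permutation p = 4e-05, adjusted 8e-05), with r = 0.74 without chromosomes 17 and 19. This was not seen in the aphidicolin libraries of set 3: r = -0.04 (permutation p = 0.872, adjusted 0.938) and rho = 0.12 (permutation p = 0.592, adjusted 0.621) in K562, and r = 0.16 (permutation p = 0.476, adjusted 0.714) and rho = 0.44 (permutation p = 0.0341, adjusted 0.0585) in 2A3, with r = 0.25 and 0.40 without those chromosomes. Untreated γH2AX of sets 1 and 2 had r = -0.29 (permutation p = 0.131, adjusted 0.225) and rho = -0.33 (permutation p = 0.123, adjusted 0.164), and r = -0.18 without those chromosomes. For the list left after sh-mH1.2 r was -0.01 (permutation p = 0.938, adjusted 0.938) and rho 0.11 (permutation p = 0.621, adjusted 0.621), with r = 0.16 without them.

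MacroH2A islands covered more of the genome under aphidicolin, and deeper libraries could give longer lists. Setting the lists to equal covered length did not remove the changed positions. That weakens a longer list that only extends to weaker places as their whole cause, but does not exclude it. Only 2 other splits exist for each target, too few for a test, and equal covered length does not make read depth equal. Reads per kb of island under aphidicolin were 0.897 times the untreated value for macroH2A1.2 and for macroH2A1 (exact permutation p = 0.333 each). A lower value is what lists reaching weaker places would give, though unknown depth also sets it. With equal covered length the aphidicolin split of macroH2A1.2 changed 68.9 Mb against 12.4 Mb in the larger of the other 2 splits, a ratio of 5.53, and that of macroH2A1 31.6 Mb against 16.5 Mb, a ratio of 1.91. For macroH2A1 the same setting lowered the changed length from 54.8 Mb, left gains and losses near equal (16.4 and 15.2 Mb) and took the limma calls from 852 and 14 windows to 4 and 0 (800 and 891 at an unadjusted p under 0.05; edgeR without that setting 14 and 0, DESeq2 2436 and 2715), so its mostly upward change was not kept. The gain in total length itself stays open, since library depth is unknown and equal covered length removes it by construction. An effect of replication stress on where macroH2A lies stays among the open explanations, untested here.

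Chance as the origin of the window counts was tested on other splits of the libraries. For γH2AX, 3 of 100 splits of the 10 libraries (the real one included) gave at least the real 691 windows. The highest other split gave 5577 and put both aphidicolin libraries of set 1, aphidicolin replicate 1 of set 2 and both libraries of set 3 together, which points to a structure of these samples beside treatment: it differs from the real split by exchanging aphidicolin replicate 3 of set 2 and the untreated library of set 3. In title sets 1 and 2 alone limma called 2306 windows higher and 1028 lower. For both macroH2A antibodies in 1 fit, 1 of 34 splits of the 8 libraries, the real one, gave 2672 windows and the highest other gave 1, while 1 further split could not be fitted. With equal covered length that fit gave 64 windows higher and 115 lower. Many of these splits divide the title sets, and so for macroH2A the antibodies, unevenly. Of the splits that exchange libraries only within title sets, 1 of 36, the real one, gave as many as 691 for γH2AX, with 4 in the highest other. That argues against chance for that count but does not exclude it. It is the smallest share these splits can give, and they were chosen after seeing the data. The count was also unstable, with 18 windows higher and 0 lower by limma with the replicate number as a block. For macroH2A there are 18 such splits, too few for a share under 0.05, with 2672 in the real one and 0 by limma in the others.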
